A study of Drosophila simulans with 4 samples.

How the data were processed

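Small RNA was sequenced from 4 libraries of Drosophila simulans, 1 per group, with no replicate. Ovaries of 3-day-old females came from the strains Chicharo and Makindu. Eggs of 0 to 2 hours came from the reciprocal crosses, called NRT (Chicharo mothers, Makindu fathers) and RT (Makindu mothers, Chicharo fathers). Flies were kept at 18 °C and RNA of 18 to 30 nt was cut from a gel, per the labels' protocols. The submitters' processing notes name CASAVA 1.8 and Novoalign, the latter with no version. The genome build and the role of each tool were not given in the sources used here.

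The deposited values were raw read counts per distinct sequence, whole numbers with no normalization. The libraries held 35838725 reads (Chicharo ovary), 37727472 (Makindu ovary), 15750210 (NRT eggs) and 12103531 (RT eggs), of 19 nt or longer. Reads with an undetermined base made up between 0.191% and 0.238% of each library and were left out of the contig work. No genome was used here. The planned counts per annotated gene, per 5 kb window and in the flamenco and 42AB piRNA clusters were therefore not analysed here, and neither were tirant by name nor the lists of messenger RNA genes.

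In place of annotated genes, contigs were built from the piRNA-size reads (23 to 29 nt) of all 4 libraries, a choice made after the data were examined. These reads were taken by length, and fragments of other RNAs of that size were not removed. Sequences with at least 2 reads were joined by shared words of 17 nt on either strand. A contig started from a word with at least 20 reads, looked 20 nt ahead at a branch and was kept from 150 nt. This gave 1599 contigs with 546556 nt, on which 57.6%, 61.3%, 58.5% and 59.7% of the piRNA-size reads had an exact match, in the order of the libraries above. Each word was used once, so a placed read had exactly 1 place. Related copies or strain variants of an element fall into separate contigs only where their own words extend to 150 nt. Closer variants form no contig, and an exact match leaves their reads unplaced. With up to 1 mismatch 70.0%, 73.7%, 71.2% and 72.4% were placed, in the same order. A ratio between strains on exact matches can therefore reflect sequence differences as well as amounts. Counting uniquely placed reads alone was planned and changes nothing by this construction, so it says nothing about stability. Related contigs were found with bwa 0.7.19 as pairs with at least 60 aligned nt, and each contig was also counted together with its relatives.

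Open reading frames of at least 60 amino acids were searched for short protein motifs of retroelements. The 55 contigs with a motif were classed as Ty3/gypsy-type, LINE-type, BEL-type or Env-type and oriented by that frame. The motifs were chosen after the data were examined, and a class names a motif, not an element. The miRNAs were counted as reads of 21 to 24 nt whose first 18 nt equal those of 1 of 66 mature sequences. These were written from general knowledge of Drosophila miRNAs after the data were examined. A miRNA that differs in this species, or whose sequence was written wrongly, is therefore undercounted. Of these sequences 6 matched no read in any library (miR-9b, miR-9c, miR-79, miR-277, miR-305 and miR-306), and the reason was not tested. The miRNA shares, and the scale by miRNA reads, are therefore too low by an unknown amount if these miRNAs are present under other sequences. The miRNA lists (follicle-enriched, miR-309 cluster, miR-310 cluster, let-7 complex, muscle, and other ovary or egg miRNAs) were fixed in advance.

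Ratios are log2 ratios of read counts per 1000000 deposited reads, with a pseudocount of 0.5 reads and at least 100 reads over the 2 libraries compared. With 1 library per group no test was made. Intervals are exact at 95% (Poisson for counts, Clopper-Pearson for shares, conditional binomial for ratios) and cover the counting error of reads only. Reads amplified without molecular identifiers are not independent molecules, so for molecules these intervals are too narrow. A ratio compares 2 libraries, not the conditions, and has no replicate check. The median of a list is given with its percentile among 10000 random lists of the same size matched on read number, as a description. Random lists were drawn from all measured contigs or miRNAs, members of the list included, and related contigs counted as separate. Contigs were named by rule: the 10 with most reads, and per comparison the 5 with the highest and the 5 with the lowest ratio among those with at least 500 reads and beyond 2-fold. This applies to contigs a rule fixed for annotated genes before the data were examined, and its condition on uniquely placed reads had no effect. Up to 4 contigs per motif class, those with most reads, were added after the data were examined. Of the miRNAs the rule took the 10 with most reads and 2 to 4 members of each list, those with most reads first, or 1 where a list had 1 member. Any other contig or miRNA singled out was chosen after its values were seen.

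Alternatives were TMM (edgeR 4.0.16) and median-of-ratios (DESeq2 1.42.0) factors and miRNA reads as the scale, up to 1 mismatch, reads of 24 to 28 nt, other read minimums and pseudocounts, and each distinct sequence counted once. Chosen after the data were examined were words of 18 nt, related contigs together, ping-pong on contig positions, and scaling without 2S rRNA. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88, numba 0.67.0, matplotlib 3.10.9 and R 4.3.3 were used. On simulated reads of 200 sequences, all contigs were true substrings. For the ovary comparison, simulated 4-fold and 8-fold changes came back at log2 medians of 1.99 (50 contigs) and 3.01 (50 contigs). All 60 simulated related pairs of 5 to 15% divergence were found. These copies were aligned as whole sequences and did not pass through the assembly. The check therefore does not cover copies or strain variants that formed no contig. Since the 200 sequences were unrelated, joins between related elements were not checked either.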

Results

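Small RNAs of ovaries from 2 Drosophila simulans strains, Chicharo and Makindu, and of early eggs from their reciprocal crosses were compared. The design concerns piRNAs of tirant, an endogenous retrovirus-like element, and what mothers place in their eggs. Each group was 1 library, so values carry counting error only and no difference has a replicate check. Depth ran from 12103531 reads (RT eggs) to 37727472 reads (Makindu ovary).

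Reads of piRNA size made up most of each library and a larger share in eggs than in ovaries. The 23 to 29 nt class held 64.2% of reads in Chicharo ovaries, 71.8% in Makindu ovaries, 85.6% in NRT eggs and 87.2% in RT eggs. The 95% Clopper-Pearson interval of the RT egg share, from the library with fewest reads, was 87.21 to 87.25%. The most frequent piRNA length was 26 nt in both ovaries and in RT eggs, and 25 nt in NRT eggs. A first U, typical of primary piRNAs, was present in 67.3%, 65.1%, 72.8% and 72.6% of these reads in the same order. Reads that matched 1 of 66 miRNA sequences held 26.5%, 23.1%, 14.0% and 12.6% of the libraries, with no match for 6 of the sequences.

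**Figure D1:**
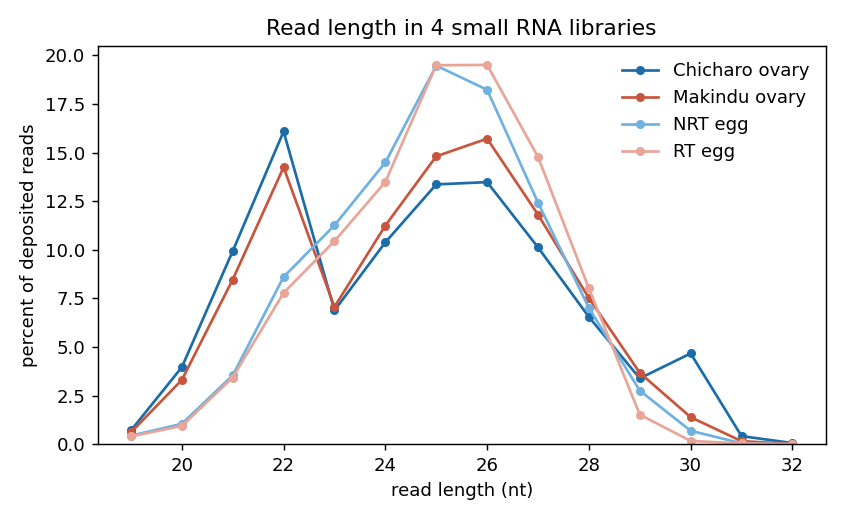
Read length (nt, x axis) against percent of deposited reads (y axis) for the 4 libraries, 1 line each. Ovaries have a separate peak at 22 nt, with 16.1% of Chicharo and 14.2% of Makindu reads, where eggs have 8.60% (NRT) and 7.78% (RT) and no separate peak.

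The ping-pong signature, an excess of piRNA pairs on opposite strands whose first 10 nt are complementary, was present in each library. Complementary first 10-mers were 23.4 times as frequent as random words in Chicharo ovaries, 27.5 times in Makindu ovaries, 16.5 times in NRT eggs and 16.1 times in RT eggs. Means over the other offsets were 3.92, 3.78, 3.65 and 3.23. The Z of the 10-nt overlap was 2.49, 3.48, 1.90 and 2.98 with reads weighted, where a second peak at 12 nt exceeded the 10-nt peak in all libraries but that of Makindu ovaries. On contig positions 65.4%, 68.5%, 61.9% and 61.8% of placed reads had a partner at 10 nt, against means of 26.9%, 30.9%, 25.7% and 25.6% at other overlaps. With each distinct sequence counted once the excess was smaller, with ratios of 3.16, 3.23, 3.26 and 3.36 against means of 1.95, 2.01, 2.04 and 2.19, and on contig positions 34.6%, 36.9%, 33.2% and 32.7% against 26.2%, 29.2%, 25.2% and 24.6%.

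The comparison of ovaries asks how the piRNAs of the strains differ. Of 1599 contigs, 221 were beyond 2-fold higher in Makindu ovaries, 246 were beyond 2-fold lower and 1132 lay within. The highest ratio was that of contig-354 (383 nt), with 16235 reads in Makindu and 167 in Chicharo ovaries, a log2 ratio of 6.52 (6.31 to 6.76). Its most frequent read was AGATTGACACAAATAATGCTGACGCGCT. The lowest was that of contig-1228 (181 nt), with 9 and 5850 reads, a log2 ratio of -9.34 (-10.55 to -8.49). Counted with 1 related contig each, contig-354 had a ratio of 3.13, contig-366 had 1.05 in place of 5.53 and contig-1074 had 1.63 in place of 6.40. No related contig was found for contig-478 (5.87), contig-1485 (5.97), contig-825 (5.67) or the 5 lowest contigs, among them contig-954 (-9.11), contig-642 (-8.25), contig-734 (-8.17) and contig-552 (-7.80). A close strain variant that formed no contig of its own would not be found this way. With up to 1 mismatch these contigs had ratios of 5.52 to 5.86 and of -9.08 to -7.81.

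Contigs with retroelement motifs lay mostly within 2-fold between the ovaries, as did 22 of 26 LINE-type and 19 of 21 Ty3/gypsy-type contigs. LINE-type contigs, from elements that copy themselves through an RNA without long terminal repeats, had a median log2 ratio of 0.16 at percentile 21.7 of matched random lists. Beyond 2-fold, 3 of them were higher, contig-75 at 4.18 (4.13 to 4.24), contig-38 at 1.51 and contig-168 at 1.16, and contig-1187 was lower at -1.03, but within 2-fold with TMM factors and per miRNA read (-0.83). The Ty3/gypsy-type list had 2 higher and 0 lower, contig-30 (1362 nt) at 1.17 (1.15 to 1.19) and contig-853 at 1.16, or 0.91 with its related contig, with a median of 0.15 at percentile 57.4. The LINE- or Ty3/gypsy-type contig-75, contig-38, contig-168, contig-1187 and contig-853 were chosen after their values were seen. Of 4 Env-type contigs, whose motif is that of retroviral envelope proteins, 2 were lower in Makindu, with a median of -0.78 at percentile 3.04, and 1 of them, contig-1030, was within 2-fold per miRNA read and with reads of 24 to 28 nt (-0.92 and -0.88). Contig-132 (662 nt) had 25590 reads in Makindu and 77653 in Chicharo ovaries, a ratio of -1.68 (-1.70 to -1.66), contig-1030 had -1.13, and contig-58 (981 nt) had 0.27 (0.24 to 0.30), or 0.94 with its 2 related contigs. The 4 BEL-type contigs had a median of -0.61 at percentile 2.09, with contig-71 at -1.13, contig-271 at -1.17 and contig-8 at -0.035, and per miRNA read contig-71 (-0.93) and contig-271 (-0.96) were within 2-fold too. Which of these, if any, belongs to tirant was not analysed here. Neither was whether the 4 Env-type or the 4 BEL-type contigs are pieces or copies of the same element. If they are, their percentiles overstate how unusual the class is.

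Reads against the motif frame prevailed in each library over the motif contigs as a set. Over the 55 motif contigs the antisense share was 77.9% in Chicharo ovaries, 81.3% in Makindu ovaries, 78.4% in NRT eggs and 83.3% in RT eggs. By class it ran from 58.2% (57.9 to 58.4) for BEL-type contigs in RT eggs to 92.5% (92.4 to 92.7) for Env-type contigs in Chicharo ovaries. For Ty3/gypsy-type contigs it was 81.8% in Chicharo and 88.4% in Makindu ovaries, and for LINE-type contigs 78.1% and 83.1%. BEL-type contig-71 and contig-97 had mostly sense reads in all 4 libraries, with 9.87% (9.61 to 10.1) and 30.0% (29.5 to 30.5) antisense reads in Chicharo ovaries, and contig-8 held 361776 of the 453841 BEL-type reads there. Among contigs with most reads, LINE-type contig-9 (2503 nt) had 475541 reads in Makindu and 277845 in Chicharo ovaries, a ratio of 0.70. Contig-10 (2471 nt, no motif) had a ratio of -1.26, or -0.92 with its 2 related contigs.

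Eggs of the reciprocal crosses share their parents' strains and differ in which strain was the mother. Of 1524 contigs, 227 were beyond 2-fold higher in RT eggs (Makindu mothers), 259 lower and 1038 within. The larger side depended on the scale, with 249 higher and 228 lower under median-of-ratios factors and 271 and 217 per miRNA read. The highest was contig-825, with 1984 reads in RT and 90 in NRT eggs, a log2 ratio of 4.83 (4.54 to 5.16). The lowest was contig-1289, with 23 and 1117 reads, a ratio of -5.19 (-5.89 to -4.63). In the egg comparison, Env-type contigs had 3 of 4 members lower, with a median of -1.28 at percentile 0.93, and BEL-type contigs 2 of 4, with a median of -0.80 at percentile 1.68. The Env-type ones were contig-1030 (-2.72), contig-132 (-1.32) and contig-94 (-1.24, or -0.69 with its related contigs), while contig-58 had 0.43, or 1.32 with its 2 related contigs, and the BEL-type ones contig-71 (-1.37) and contig-271 (-1.31). LINE-type contigs had 2 of 26 higher, contig-75 (2.46) and contig-168 (1.55), and 3 lower, contig-1058 (-1.89), contig-42 (-1.80, or -0.61 with its related contigs) and contig-152 (-1.09, or -0.14), with a median of -0.0015 at percentile 29.1. Ty3/gypsy-type contigs had 3 of 21 higher, contig-853 (1.18, or 0.91 with its related contig), contig-30 (1.05, or 0.89 with 1 mismatch) and contig-408 (1.05, or 0.29 with its related contig), the latter pair within 2-fold with TMM factors (both 0.99), and 1 lower, contig-363 (-1.28, but 0.21 with its related contig), with a median of 0.22 at percentile 86.3. The LINE- or Ty3/gypsy-type contig-1058, contig-42, contig-152, contig-408 and contig-363 were chosen after their values were seen.

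Differences between eggs followed those between the mothers' ovaries. Across 1524 contigs, which are not independent replicates, Pearson's r of the egg ratio with the ovary ratio was 0.856 (bootstrap over contigs 0.838 to 0.875) and Spearman's rho was 0.828, with no library shared by the ratios. Across 25279 piRNA 5' ends, r was 0.898 and rho 0.901. Of 221 contigs higher in Makindu ovaries and 227 higher in RT eggs, 156 were shared, against 32.9 for independent lists. Of 237 and 259 lower ones 188 were shared, against 40.3, and 0 contigs were beyond 2-fold in opposite directions. The 40 contigs with ovary ratios at or under -3 had a median of -4.29 in ovaries and -3.24 in eggs, and the 45 above 3 had medians of 3.76 and 2.95. Sequences nearly absent from mothers' ovaries still reached 7.08% (RT eggs) and 6.19% (NRT eggs) of their level in the other cross, as given below. This can limit the size of an egg ratio. Contig-1228 had -9.34 in ovaries and -3.87 in eggs, and contig-354 had 6.52 and 3.91. How much of the smaller egg ratios comes from this was not tested.

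**Figure D2:**
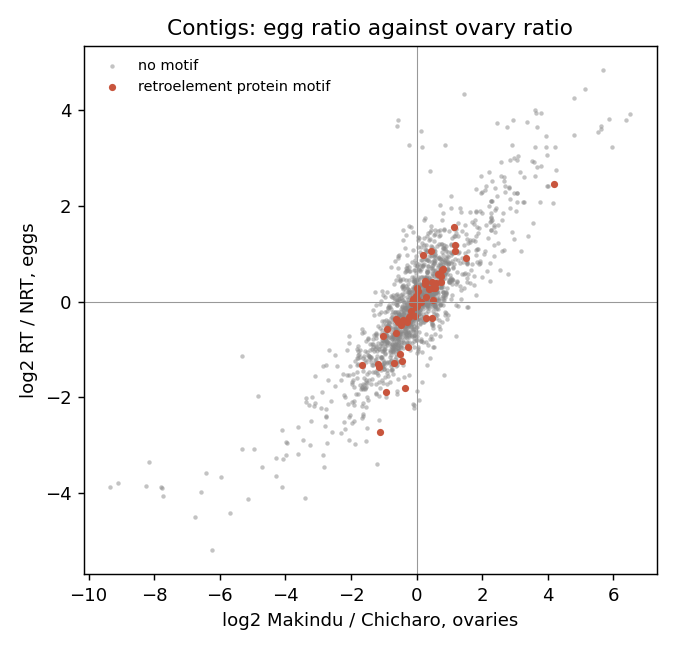
Each point is 1 of 1524 contigs; the x axis is the log2 ratio of Makindu to Chicharo ovaries and the y axis that of RT to NRT eggs. Points lie along a rising line with a slope of 0.711, and contigs with a retroelement motif lie mostly near the centre.

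Each egg library was set against the ovaries of its mother's strain. The median contig ratio was 0.45 in NRT eggs over Chicharo ovaries and 0.32 in RT eggs over Makindu ovaries, so contigs as a whole lay above 0 under this scaling, where both comparisons of like tissues had a median of -0.05. Beyond 2-fold, 298 contigs were higher and 206 lower of 1593 in NRT eggs, and 279 higher and 224 lower of 1585 in RT eggs. This split depended on the scale, with 138 higher and 247 lower in NRT eggs under median-of-ratios factors, and 1092 and 146 per miRNA read. In RT eggs it was 189 and 257 under median-of-ratios factors, 142 and 287 under TMM factors and 946 and 130 per miRNA read. The higher contigs include some nearly absent from the mother's strain. Contig-354 had 3.01 in NRT eggs, with 167 reads in Chicharo and 16235 in Makindu ovaries. Contig-1228 had 5.42 in RT eggs, with 9 reads in Makindu and 5850 in Chicharo ovaries. Sequences of this kind reached 6.19% (NRT) and 7.08% (RT) of their level in the other cross, as given below. Such a share can raise an egg ratio, and how many higher contigs it affects was not tested. Follicle-enriched miRNAs held 57.8% of miRNA reads in Chicharo and 53.1% in Makindu ovaries. In NRT and RT eggs they held 0.594% and 0.178%. The miRNA scale thus itself differs between ovaries and eggs, so a ratio of egg to ovary per miRNA read also carries this loss. Of 1579 contigs measured in both crosses, 152 were higher in both (51.0 for independent lists) and 168 lower in both (29.2). Contig-1234 and contig-1328, singled out after their values were seen, were lower in NRT and higher in RT eggs, at -1.01 and 1.89, and -1.06 and 3.14, but both were within 2-fold in NRT eggs per miRNA read (-0.083 and -0.13). The most reduced named contigs were nearly absent from eggs. Contig-1335 had 10040 reads in Chicharo ovaries and 11 in NRT eggs, a ratio of -8.58 (-9.65 to -7.81), and contig-281 had 14241 and 26, a ratio of -7.88 (-8.53 to -7.36). In RT eggs contig-281 had a ratio of -6.96 and contig-735, with 3 reads, of -8.23 (-10.73 to -6.90). Contig-1472 had 1 read in NRT eggs and a ratio of -8.98 (-14.87 to -7.08), but -2.68 with its related contig.

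Retroelement-motif contigs were compared with the median of all contigs in eggs, 0.45 in NRT and 0.32 in RT eggs. The Ty3/gypsy-type median was 0.30 in NRT eggs (percentile 19.2) and 0.21 in RT eggs (percentile 38.1). LINE-type medians were 0.53 (percentile 70.4) and 0.39 (percentile 77.1), and BEL-type medians 0.33 (percentile 36.2) and 0.28 (percentile 51.5). Env-type medians were -0.19 (percentile 9.39) and -0.65 (percentile 5.18), and both were above 0 per miRNA read, while the Ty3/gypsy-type and BEL-type medians in RT eggs were under 0 with TMM factors. Beyond 2-fold in NRT eggs, Ty3/gypsy-type contig-18 (1.02) and contig-853 (1.09) and LINE-type contig-75 (1.59), contig-1058 (1.06) and contig-17 (1.04) were higher, and contig-318 (-1.08, or -0.77 with its related contig) of the Ty3/gypsy type was lower. Of the higher ones, those other than contig-75 were within 2-fold under median-of-ratios or TMM factors, and contig-853 had 0.43 with its related contig. Contig-75 had 2489 reads in Chicharo and 47663 in Makindu ovaries. Makindu sequences nearly absent from Chicharo ovaries reached 6.19% of their RT level in NRT eggs. A share of that size can raise the NRT egg ratio of contig-75 too, and by how much was not tested. In RT eggs contig-17 (1.06), contig-853 (1.11) and contig-833 (1.05) were higher, but within 2-fold under median-of-ratios or TMM factors, and contig-853 had 0.44 with its related contig. LINE-type contig-42 (-1.29, or -0.68 with its related contigs) and Env-type contig-1030 (-1.34) were lower. Per miRNA read contig-318, contig-42 and contig-1030 were within 2-fold, as were contig-21 below in both crosses and contig-94 below in NRT eggs. That scale raises the ratios of all contigs alike, to medians of 1.37 in NRT and 1.198 in RT eggs. More motif contigs are then beyond 2-fold higher than those named here, and they were not counted. The LINE- or Ty3/gypsy-type contig-17, contig-318 and contig-833 were chosen after their values were seen. Ty3/gypsy-type contig-21 (1565 nt) had ratios of -1.38 and -1.70, with 98.4% of its ovary reads on 1 strand. Env-type contig-94 (781 nt) had ratios of -1.43 and -2.24, or -0.87 and -1.09 with its 2 related contigs, and its antisense share was 81.3% (80.7 to 81.8) in Chicharo ovaries and 32.2% (30.6 to 33.8) in NRT eggs, and 91.8% (91.4 to 92.2) in Makindu ovaries and 49.3% (46.2 to 52.4) in RT eggs.

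Ovary reads of contigs that were low in eggs came almost entirely from 1 strand. Of 76 contigs at least 8-fold lower in both egg libraries, among 1443 with 1000 ovary reads or more, 75 had at least 95% of their ovary reads on 1 strand, and contig-1309 had 93.9%. These limits were chosen after the values were seen. The 234 one-strand contigs had median egg ratios of -1.98 (NRT) and -1.54 (RT), and the other 1209 had 0.50 and 0.38. Not all one-strand contigs were low: 32.1% were at least 8-fold lower in both egg libraries, and their upper quartiles were -0.042 (NRT) and -0.12 (RT).

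**Figure D3:**
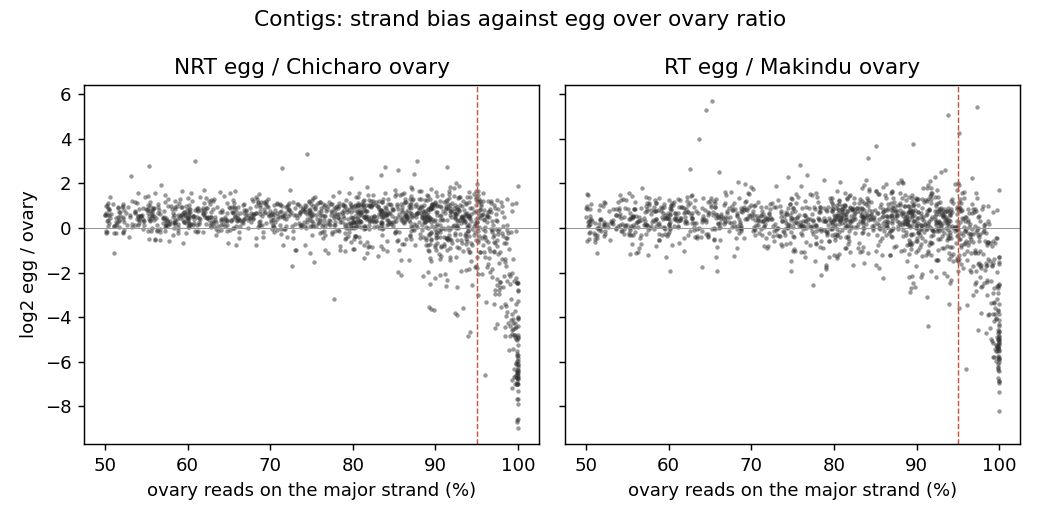
Each point is 1 of 1443 contigs; the x axis is the percent of ovary reads on the major strand and the y axis the log2 ratio of NRT eggs to Chicharo ovaries (left) or RT eggs to Makindu ovaries (right). The dashed line marks 95%, and the lowest egg ratios lie to its right.

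The miRNAs separated eggs from ovaries more than strain from strain. Follicle-enriched miRNAs, named for the somatic cells around the oocyte, were lower in eggs for 3 of 3 members in both crosses, with medians of -6.85 in NRT eggs (percentile 2.80) and -8.64 in RT eggs (percentile 2.80). They included miR-989, at a normalised read count (per 1000000 deposited reads) of 82038 in Chicharo ovaries and 189 in NRT eggs, and miR-318, at 64780 and 559.7. The median of all 59 miRNAs was 0.41 in NRT and 0.54 in RT eggs. The let-7 complex, a set of developmental timing miRNAs, was lower for 3 of 3, with medians of -7.48 (percentile 0.39) and -7.93 (percentile 0.335). The miR-309 cluster, whose members are transcribed by the early embryo, was higher for 5 of 6, with a median of 7.55 in NRT eggs (percentile 100) and a median 512-fold ratio in RT eggs (percentile 99.995). Here miR-309 itself had ratios of 8.36 (8.13 to 8.62) and 9.98 (9.61 to 10.40), and miR-4 had 8.52 and 9.49. The remaining member, miR-6, had -2.05 and -0.23, and 0.64 in RT eggs per miRNA read. It is counted by a sequence that can differ in this species or be written wrongly. Members of the miR-310 cluster were higher for 4 of 4 in NRT and 3 of 4 in RT eggs, with medians of 1.67 (percentile 77.3) and 1.95 (percentile 79.5). The muscle miRNA miR-1 had ratios of 1.53 (percentile 95.6) and 1.69 (percentile 70.9). Among other ovary or egg miRNAs 14 of 42 were higher and 14 lower in NRT eggs (median 0.33, percentile 28.8), and 16 and 10 in RT eggs (median 0.49, percentile 19.3). Per miRNA read these were 25 and 7 in NRT and 25 and 5 in RT eggs. With 59 miRNAs measured, the random lists draw on a small pool that holds the members of the list itself. This limits how extreme a percentile can be, so percentiles do not rank the lists.

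**Figure D4:**
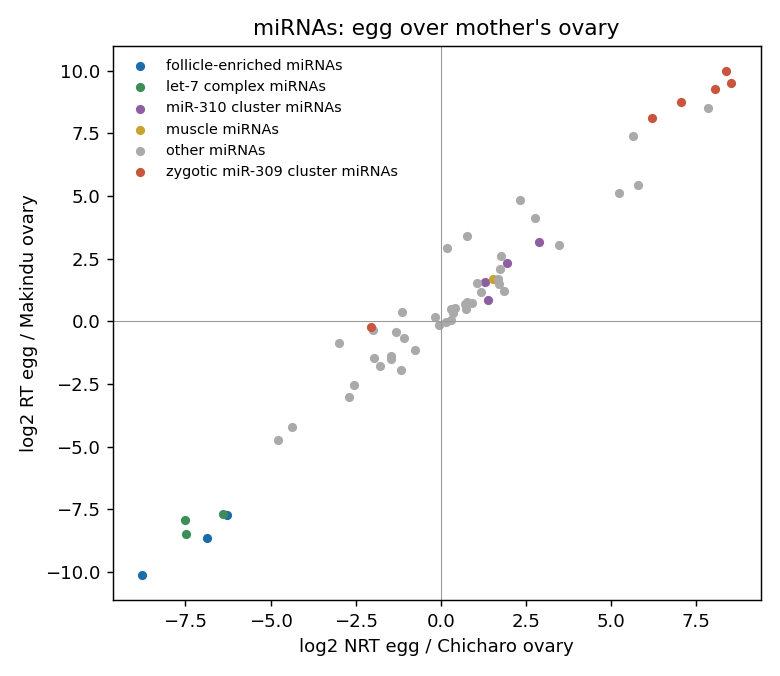
Each point is a miRNA with at least 100 reads in both pairs; the x axis is the log2 ratio of NRT eggs to Chicharo ovaries and the y axis that of RT eggs to Makindu ovaries. Follicle-enriched and let-7 complex miRNAs lie at the lower left, with list medians of -6.85 and -7.48 on the x axis, and 5 of 6 miR-309 cluster members at the upper right.

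Between the ovaries 9 of 57 miRNAs were beyond 2-fold lower in Makindu and 0 were higher, against a median of -0.17 for all. They were led by miR-10 (-2.57, -2.62 to -2.52), miR-314 (-2.28) and miR-252 (-2.22), and included 5 of 6 of the miR-309 cluster (median -1.28, percentile 6.5), such as miR-286 at -1.80. This cluster was a trace in ovaries, with 0.0792% of miRNA reads in Chicharo and 0.0310% in Makindu. In NRT and RT eggs it held 14.2% and 17.7%. Reads of miR-309 itself numbered 138 and 55 in Chicharo and Makindu ovaries. The source of such small amounts was not tested. Per miRNA read miR-278, miR-3 and miR-6 were within 2-fold. Named outside the rule, miR-10, miR-314, miR-252 and miR-278 were chosen after their values were seen. List medians were -0.22 (percentile 2.62) for follicle-enriched miRNAs, -0.091 (percentile 73.6) for the miR-310 cluster, -0.19 (percentile 35.2) for the let-7 complex, -0.36 (percentile 22.8) for miR-1 and -0.11 (percentile 98.2) for the others. Per miRNA read the medians of the miR-310 cluster, the let-7 complex and the others were above 0, as were miR-311, let-7 and miR-125.

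Between the eggs 4 of 58 miRNAs were beyond 2-fold higher in RT and 5 lower. The 3 follicle-enriched miRNAs were lower in RT eggs, with a median of -1.81 (percentile 0.355), as were the 2 measured let-7 complex members, with a median of -1.32 (percentile 2.35). Both lists were small remainders in eggs. Follicle-enriched miRNAs held 0.594% of miRNA reads in NRT and 0.178% in RT eggs, against 57.8% and 53.1% in Chicharo and Makindu ovaries. The let-7 complex held 0.027% and 0.0126%, against 2.05% and 2.09%. What sets a ratio between such small amounts was not tested. The miRNAs higher in RT eggs were miR-276b (1.25), miR-276a (1.13), miR-278 (1.08) and miR-iab-4 (1.04), chosen after their values were seen. Medians were 0.19 (percentile 82.7) for the miR-309 cluster, 0.20 (percentile 93.7) for the miR-310 cluster, -0.20 (percentile 41.2) for miR-1 and -0.026 (percentile 33.9) for the others, the latter above 0 per miRNA read.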

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

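Of the tests of the third pattern, the share of reads with a 10-nt partner, the 10-nt excess over all one-strand contigs and the 1-mismatch test were set before their values were seen; all other tests here were chosen after their result was seen.

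Contig-1234 had a log2 ratio of 1.89 in RT eggs over Makindu ovaries and -1.01 in NRT eggs over Chicharo ovaries, and contig-1328 had 3.14 and -1.06. Both were singled out because the crosses differed in direction, and the difference was not tested; per miRNA read both were within 2-fold in NRT eggs (-0.083 and -0.13). For the same reason miR-278 stood out, with 1.08 in RT over NRT eggs and -1.02 in Makindu over Chicharo ovaries (-0.82 per miRNA read), also not tested. Reads longer than the 30-nt limit of the gel were 0.495% of reads in Chicharo ovaries, 0.174% in Makindu ovaries, 0.0498% in NRT eggs and 0.0451% in RT eggs. They stood out because the gel was meant to hold none, and were compared only for the 2S ribosomal RNA below.

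Sequences with 500 or more reads in the ovaries of one strain and at most 10 in the other were found in eggs whose mothers lacked them. Those of Chicharo reached 7.08% of their NRT level in RT eggs, and those of Makindu 6.19% of their RT level in NRT eggs, with 6.998% and 5.60% for sequences with 0 reads in the other ovaries. Carry-over at that share between all libraries would set a floor for each sequence, and the tables argue against it: of the sequences with 500 reads or more, 542 of 5258 in Chicharo and 844 of 6591 in Makindu ovaries had at most 10 in the other ovaries, against at most 0.0136 expected with such a floor, and for sequences chosen by the eggs the median share between ovaries was at most 0.219 times the pooled egg share. The pooled ovary share, computed first, was 0.854 and 0.302 times the egg share (0.418 and 0.191 without the 26 and 25 sequences with most reads there), which by itself would not exclude carry-over, and the median and the floor were taken only after this was seen. Carry-over between the egg libraries alone was not tested and stays open, as does, as a hypothesis, admixture of about that share of the other cross (SD of the log2 share 0.813 and 0.549, against 0.316 and 0.274 from counting, and 0.903 and 0.302, against 0.339 and 0.307, for sequences with 0 reads in the other ovaries), and the father's genome cannot be told apart from it: the pooled shares differed by 1.14-fold, less than the 2-fold set for that explanation, but the spread above counting in both crosses for sequences with at most 10 reads kept it from being excluded.

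The 2S ribosomal RNA made up 3.53% of reads in Chicharo ovaries and 0.402% in Makindu ovaries, and its 30-nt form was 9.34-fold higher in Chicharo. A gel slice that reached longer RNA would raise other 30-nt reads too, and these were 1.21-fold higher, which argues against it as the whole cause. Other reads longer than 30 nt were 2.46-fold higher in Chicharo, and NRT eggs had 18.2-fold more 30-nt 2S rRNA and 3.76-fold more other 30-nt reads than RT eggs, so a part due to the slice stays open. More broken ribosomal RNA would raise 2S fragments of 19 to 28 nt, and these were 1.40-fold higher, which argues against it as the whole cause. Removal of 2S rRNA during library preparation, and the strain itself, stay open and were not tested.

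Contigs with ovary reads on 1 strand were lower in eggs than the other contigs in the median, but 32.1% of them were at least 8-fold lower in both egg libraries, and their upper quartiles were -0.042 and -0.12. A change of scale moves all contigs alike, and the gap to the other contigs was at least 1.92 on the log2 scale. Each egg library was set against ovaries of its mother's strain, so variants of that strain would lower the placement of both alike. Variants in the eggs with 1 changed base would narrow the gap with 1 mismatch, and it stayed at 1.71 or more. Variants with more changes were not covered by that test. A candidate explanation, as a hypothesis, is that they are made in ovary cells other than germ cells, which lack ping-pong, such as the follicle cells of miR-989 (82038 reads per 1000000 in Chicharo ovaries, 189 in NRT eggs): the 10-nt excess over other overlaps in egg-low one-strand contigs was 0.532 times that of the other one-strand contigs (1.18 against 2.21), and 1.196 against 2.22 in the 12 of 75 and 101 of 159 contigs with at least 100 reads on the other strand, so it rests on few of the egg-low contigs. The share of reads with a partner, 0.237 times that of both-strand contigs, was tested first and decides nothing, because few reads on the other strand fix it. Fragments of other RNAs of piRNA size were not removed, so whether the egg-low contigs hold piRNAs was not tested. A retroelement motif was found in 0 of the 76 contigs at least 8-fold lower in both egg libraries. Among the 1209 both-strand contigs 51 had one.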

How the results depend on the processing

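Words of 18 nt, related contigs together, ping-pong on contig positions and scaling without 2S rRNA were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Counting uniquely placed reads alone was void, since each placed read had 1 place, and is counted nowhere here. Not run for want of a genome were the planned settings for cluster regions and 5 kb windows. Counts of contigs beyond 2-fold between strains and between crosses stayed within 1.5 times under each setting run, but the ovary split of 221 higher and 246 lower became 288 and 191 per miRNA read, and the egg split of 227 and 259 became 249 and 228 under median of ratios and 271 and 217 per miRNA read. Against ovaries, NRT eggs had 138 contigs higher (247 lower) under median of ratios, 149 (241) under TMM and 1092 (146) per miRNA read; RT eggs had 189 (257), 142 (287) and 946 (130). The median of all contigs, 0.45 and 0.32, was then 0.18 and 0.12, 0.21 and -0.0076, and 1.37 and 1.198; per miRNA read it went from -0.053 to 0.15 between ovaries and from -0.051 to 0.10 between eggs. The correlation of egg with ovary ratios was 0.830 over contigs and 0.805 over 5' ends with 10 reads per pair, and 0.907 over 5' ends with a pseudocount of 5. In the order Chicharo ovary, Makindu ovary, NRT and RT eggs, the 10-nt Z was 27.8, 20.8, 27.5 and 17.7 with each sequence once, 52.4, 61.9, 16.97 and 24.1 with 24 to 28 nt, and 9.77, 10.1, 10.9 and 11.001 on contig positions, so its order between libraries depends on the setting. With each sequence once, 82.8%, 84.2%, 86.8% and 88.0% were of piRNA size and 65.0%, 63.2%, 68.7% and 69.0% of these began with U; with 24 to 28 nt the values were 53.9%, 61.1%, 71.6% and 75.3%, and 66.9%, 64.8%, 72.2% and 72.1%. The miRNA share at 20 to 25 nt was 29.8%, 25.7%, 14.4% and 12.9%. The antisense share with 1 mismatch was 78.2%, 81.3% and 78.9% in Chicharo ovaries, Makindu ovaries and NRT eggs, and with 24 to 28 nt 81.6%, 78.6% and 83.8% in Makindu ovaries, NRT and RT eggs. With 1 mismatch contig-1140 turned from -1.95 to 1.69 between ovaries, from -2.53 to 0.24 between eggs and from 2.15 to -0.026 in RT eggs over Makindu ovaries. Summed with its related contig, contig-363 turned from -1.28 to 0.21 between eggs. The cause was not tested for any of these. Of the other values of single contigs and miRNAs, 1076 stayed within their counting interval and 1038 left it, 426 of these under miRNA scaling.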

Other observations

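Among the list of other ovary or egg miRNAs, several had large ratios of egg to mother's ovary, given as values with no test and, for miR-1000, miR-9a, miR-iab-4 and miR-317, chosen after their values were seen. Of these, miR-1000 had log2 ratios of 7.83 (7.11 to 8.80) in NRT eggs and 8.51 in RT eggs, miR-9a had 5.78 and 5.42, and miR-iab-4, from the bithorax complex of body-plan genes, had 5.63 and 7.37. In the other direction, miR-317 had -4.78 and -4.74, and miR-263a had -2.71 and -3.02. Of the miRNAs with most reads, miR-184 had -1.18 and -1.94 (-0.25 and -1.07 per miRNA read), bantam 1.19 and 1.16, and miR-13b 0.16 and -0.020, the latter above 0 per miRNA read. The zygotic miR-309 cluster held 14.2% of miRNA reads in NRT eggs and 17.7% in RT eggs, against 0.0792% and 0.0310% in Chicharo and Makindu ovaries.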
